A study of Mus musculus with 2 samples.

How the data were processed

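Single-cell RNA sequencing was done on testis tissue from mice. There were 2 libraries, 1 per group. The label of 1 library names a high-fat diet, and the label of the other names only the tissue, so the libraries are called the high-fat library and the library whose label names no diet. Per the labels' protocols, testis pieces were digested with collagenase IV and DNase I, broken up mechanically, passed through a cell strainer and turned into barcoded libraries with a DNBelab C series kit, which captures single cells or nuclei with mRNA beads in droplets. The labels give germ cells as the cell type, but their protocols name no step that selects germ cells, and somatic cells were present in both libraries. The labels do not say whether a library holds tissue of 1 mouse or of several, nor when the libraries were made.

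The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalisation. Per the file headers, the count matrices were written by PISA 1.0. Per the submitters' processing notes, Cell Ranger 2.1.1 was used, a tool the file headers do not name. The aligner, the genome build and the annotation release are not given in the sources used here. The barcodes had been filtered before deposit, since no deposited count matrix held a barcode under 1000 UMIs (smallest totals 1000 and 1025). The library whose label names no diet had 13805 barcodes and 207667609 UMIs over 36598 genes with at least 1 count. The high-fat library had 12661 barcodes and 201842085 UMIs over 36476 genes. A gene missing from 1 library was set to 0 there, which gave 39232 genes, of which 33842 had counts in both. With ID versions removed, 35963 and 35839 of the gene IDs matched the GENCODE M21 annotation, which was used only for the kind of gene and for which genes neighbour each other. No coordinates are given, because the build behind the counts is not known.

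Cells needed at least 500 UMIs and 250 genes and at most 20% of UMIs from the mitochondrial genome, which removed 2 and 3 barcodes. Doublets were called per library with Scrublet as built into scanpy 1.11.5, at an expected rate of 6%, and left out. They numbered 518 (3.75%) in the library whose label names no diet and 462 (3.65%) in the high-fat library. The 25481 cells kept, 13285 and 12196, were scaled to 10000 UMIs, log transformed and clustered together without batch integration, on 2000 variable genes ranked over both libraries, 50 principal components, 20 nearest neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). This gave 30 clusters. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

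Clusters were named from markers of 15 cell classes. A cluster took the class with most markers among its top 10 genes by fold within a library (genes seen in at least 25% of its cells), and otherwise the class with the highest mean log2 fold over at least 3 detected markers. A cluster whose median UMI count was more than 3 times below that of its own library, with none of the name's markers among its top 10 genes, stayed without a name. The smallest marker mean of 0.25, the smallest log2 fold of 1 for a marker among the top genes and the rule for ties were set after the clusters had been seen. These rules kept clusters 3, 5, 9, 19, 26 and 29 out of the classes. Names stand for "like" in every case: a Sertoli cell here is a Sertoli-like cell by its transcripts. The myoid and endothelial cluster and the immune cluster were each clustered once more, on 1000 variable genes at resolution 0.5. No macrophage cluster formed, so the lists meant for macrophages were measured in the immune cluster, and those meant for peritubular myoid cells were measured in the myoid and endothelial cluster.

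Raw counts were summed per library and class and expressed as CPM, the counts of a gene scaled to a fixed UMI total of the class. With 1 library per group there are no replicates and no test was possible, so no p-value, standard error or number of changed genes is given, and "higher" or "lower" compares these 2 libraries, not the diets. Intervals are 95% intervals, exact Poisson for a level, exact conditional binomial for a ratio of 2 levels, exact Clopper-Pearson for a share and Newcombe for a difference of shares. They cover counting error only. Where 1 library had no count, the ratio was computed against 3 counts over the whole class and is given as a bound. The chance that a cell shows a UMI depends on its depth, so shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs, and genes per cell after thinning to 1000 UMIs in shallow classes or 2000 in deep ones.

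The study design, the markers, 34 gene lists with a home class each, the rule for named genes and most alternatives were fixed before the data were examined. For each list, the median log2 ratio (high-fat library over the library whose label names no diet) of members with at least 20 counts in the class was set beside 10000 random lists of the same size matched on mean expression over 20 bins. The percentile among these describes these libraries only. The list of insulin and leptin signalling had under 3 measured members in Leydig cells, so 33 lists have a value. They cover spermatogonial stem and progenitor genes, spermatogonial differentiation, cell division, the synaptonemal complex, meiotic recombination, the piRNA pathway, meiotic division, the acrosome, the axoneme, sperm ion transport, chromatin condensation, the outer dense fibre and fibrous sheath, glycolysis, oxidative phosphorylation, the mitochondrial genome, fatty acid oxidation, cholesterol synthesis, fatty acid and triglyceride synthesis, oxidative stress, the unfolded protein response, apoptosis, autophagy and ferroptosis, heat shock and dissociation, ribosomal proteins, the proteasome, steroid synthesis, Sertoli support, the blood-testis barrier, inflammation, the interferon response, class II antigen presentation, extracellular matrix and contractile genes.

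The rule for named genes took, per class with at least 20 cells in both libraries, the 5 highest and the 5 lowest ratios among genes with at least 100 counts (50 in a somatic class), at least 50 CPM in 1 library, at least 10% of the gene's highest CPM in any other class and a proper name, without mitochondrial, ribosomal protein and haemoglobin genes. It also took the 12 highest and 12 lowest of the whole library at 200 counts or more, and the 2 highest and 2 lowest members of each list. Other list members named below were chosen after their values had been seen.

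The calculations were tested on simulated Poisson counts per class, drawn from the real means and library sizes, with 50 genes changed at each fold. These counts hold no variation between cells. The shares below therefore test the arithmetic, not whether the intervals hold for real counts that gather in single cells. For 16804 genes of round spermatids, the 95% intervals held the true ratio of 95.6% of unchanged genes, 90% of genes set to 2 times their level, 98% at 0.5 times, 96% at 4 times and 100% at 0.25 times. For 9479 genes of Sertoli cells these shares were 96.1%, 92%, 100%, 98% and 92%, and for 723 genes of Leydig cells 96.9%, 96%, 94%, 94% and 98%. A simulated list of 20 genes had a percentile of 20.4, 81.2 and 68.8 when unchanged and of 100, 100 and 99.8 when raised 2-fold, in round spermatids, Sertoli cells and Leydig cells.

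The alternatives planned were other minima of UMIs, other mitochondrial limits, doublets kept, Leiden resolutions of 0.5 and 2, 4000 variable genes, each library clustered on its own, scaling by the median ratio of genes, cells weighted equally, cells thinned to 1 depth and other count minima for list members. The alternatives added after the data had been seen were a minimum of 2000 UMIs, genes scaled within each library before clustering, free RNA subtracted from somatic classes, the cell with the most counts left out, a clustering without 1454 marker, list and leading genes, and lists without the leading genes of clusters. The level of free RNA was taken from germ cell transcripts of at least 100 CPM, as their level in a somatic class relative to the whole library. Leydig cells were compared for expression but not for their share of cells, because the genes that define that cluster differed between the libraries and no Leydig cluster formed without them.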

Results

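Testis tissue of C57 BL/6 male mice was profiled by single-cell RNA sequencing after a diet study. In that study 20 mice, bought at 5 weeks of age and kept for 1 week of adaptation, were split into 10 on a normal diet and 10 on a diet with 60% of its energy as fat, for 12 weeks. The question was whether long feeding on fat from puberty alters the making of sperm. There were 2 libraries, 1 per group and without replicates: the high-fat library, and a library whose label names no diet. The library whose label names no diet held 207667609 UMIs in 13805 barcodes, with a median of 13024 UMIs and 3790 genes per barcode. The high-fat library held 201842085 UMIs in 12661 barcodes, with a median of 9772 UMIs and 3445 genes. After filters and doublet calls, 13285 and 12196 cells were kept. Transcripts of the mitochondrial genome made up 0.0157% and 0.0176% of all UMIs.

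The cells fell into spermatogonia-like, early and late spermatocyte-like, round and elongating spermatid-like, Sertoli-like, Leydig-like, interstitial stroma-like, myoid and endothelial-like and immune-like classes, and the shorter names stand for these from here on. Sertoli cells, the somatic cells that nurse the germ cells inside the tubule, made up 5.89% (5.50 to 6.31) of cells in the library whose label names no diet and 10.3% (9.80 to 10.9) in the high-fat library, a difference of 4.45 percentage points (3.78 to 5.12). Immune cells were 0.429% (0.325 to 0.556) against 1.61% (1.39 to 1.85), a ratio of 3.75 (2.78 to 5.12). Spermatids, the haploid cells after meiosis, were 33.3% (32.5 to 34.1) against 29.6% (28.8 to 30.4). Spermatogonia, the dividing cells at the start of the germ line, were 5.33% (4.95 to 5.72) against 7.08% (6.63 to 7.55). Myoid and endothelial cells, which form the tubule wall and the vessels, went the other way from the other somatic classes, with 0.933% (0.777 to 1.11) against 0.508% (0.390 to 0.651).

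Within the somatic cells, interstitial stroma was 1.33% (1.14 to 1.54) against 1.77% (1.54 to 2.02). Lymphoid cells, a sub-cluster of the immune cells, were 0.301% (0.215 to 0.410) against 1.56% (1.35 to 1.79), and 40 and 190 cells. Endothelial cells were 0.557% (0.438 to 0.699) against 0.262% (0.180 to 0.370), and peritubular myoid cells 0.376% (0.279 to 0.496) against 0.246% (0.166 to 0.351). All somatic classes together were 8.78% (8.31 to 9.28) against 14.8% (14.2 to 15.5). The differences for Sertoli cells, immune cells and spermatogonia were close to these when 1454 marker, list and leading genes were left out of the clustering, with 4.06, 1.18 and 1.62 percentage points. With each library clustered on its own, however, the difference in the share of cells, Spermatogonia, was 0.478 points. That for spermatids was -2.13 points without the marker, list and leading genes and -5.40 points with each library clustered on its own, against -3.66 points (-4.79 to -2.51). With 4000 variable genes the difference in the share of cells, Spermatids, was -8.543 points. Sertoli cells had a median of 1370 and 1548 UMIs, just above the smallest barcode totals of 1000 and 1025 in the files, so their share depends on where barcodes were accepted. At a minimum of 2000 UMIs their difference was 3.20 points.

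**Figure D1:**
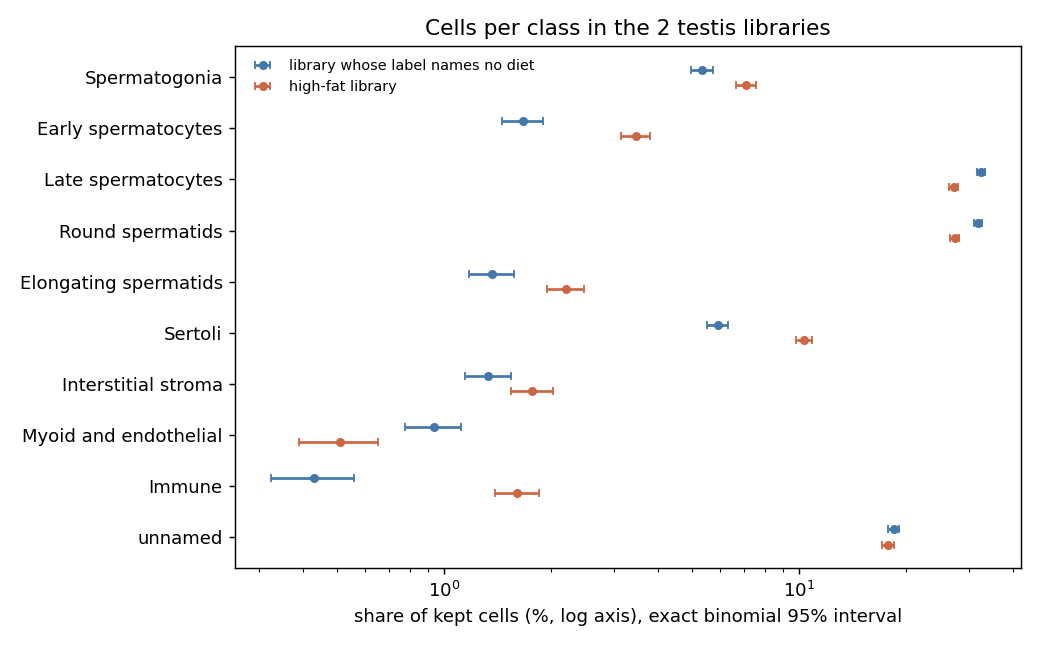
Share of kept cells (x axis, percent, log scale) in each class (y axis) for the library whose label names no diet (blue) and the high-fat library (red); points are shares and bars are exact binomial 95% intervals for counting error only. Immune cells sit at 0.429% and 1.61% and Sertoli cells at 5.89% and 10.3%, while the order of the 2 libraries for spermatocytes and elongating spermatids turned under other clustering settings.

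Along the germ line, early spermatocytes, which start meiosis, were 1.66% (1.45 to 1.90) against 3.46% (3.14 to 3.80), and late spermatocytes 32.5% (31.7 to 33.3) against 27.3% (26.5 to 28.1). Round spermatids were 31.9% (31.1 to 32.7) against 27.4% (26.6 to 28.2) and elongating spermatids 1.36% (1.17 to 1.57) against 2.21% (1.95 to 2.48). There were 6.41 (5.92 to 6.95) spermatocytes per spermatogonium in the library whose label names no diet and 4.34 (4.03 to 4.68) in the high-fat library. Round spermatids per spermatocyte numbered 0.933 (0.895 to 0.973) and 0.892 (0.851 to 0.935), and elongating per round spermatid 0.0427 (0.0366 to 0.0496) and 0.0805 (0.0708 to 0.0912). For each Sertoli cell there were 5.64 (5.23 to 6.10) spermatids in the library whose label names no diet and 2.86 (2.69 to 3.06) in the high-fat library. All these shares and ratios leave out the clusters without a name, described below. The directions for early spermatocytes, late spermatocytes, elongating spermatids and elongating per round spermatid turned under other ways of clustering. That for spermatocytes per spermatogonium turned when each library was clustered on its own (a high-fat over other ratio of 1.06). That for round spermatids per spermatocyte turned when marker, list and leading genes were left out of the clustering. Under several other settings, given below, its high-fat over other ratio was instead further below the main value. All spermatocytes together were 34.2% (33.4 to 35.0) against 30.7% (29.9 to 31.6), a difference of -3.46 points that was 4.72 points with each library clustered on its own.

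Cells left without a name were 18.4% and 17.8%. Cluster 3 held 2.66% and 8.76% of cells, cluster 5 9.56% and 0.0410%, cluster 9 5.37% and 3.28%, cluster 19 0.173% and 5.24%, cluster 26 0.587% and 0.205%, and cluster 29 0.0979% and 0.262%. Clusters 5 and 19, each almost all from 1 library, were both led by Ssxb2 and Ssxb1. These genes and Prss46 were also among the top 10 of cluster 7, which was named round spermatids. Median depth of clusters 5 and 19 was 1.22 and 1.95 relative to their own library. Germ cell shares and ratios above, and spermatids per Sertoli cell, leave these cells out and would change if they were counted as germ cells. The late spermatocytes were held mostly by clusters 2, 4 and 15 in the library whose label names no diet and by clusters 10, 13 and 18 in the high-fat library, with cluster 8 in both. The round spermatids were held mostly by clusters 6, 7 and 12 and by clusters 11, 16, 17 and 21, with cluster 14 in both. Values within these classes therefore compare clusters that each belong to 1 library.

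In the immune cells, single genes of killer T cells stood higher in the high-fat library. No list of such genes was fixed, and the make-up of the class differed, with 40 of 57 cells lymphoid in the library whose label names no diet and 190 of 196 in the high-fat library. Cd8b1 (ENSMUSG00000053044.8), a chain of the CD8 co-receptor, was at 27.3 CPM (10.0 to 59.4) against 483 CPM (425 to 546), a ratio of 17.7 (8.01 to 48.6). Ly6c2, a surface protein of activated and memory CD8 T cells and of monocytes, was at 22.8 CPM (7.39 to 53.1) against 1804 CPM (1692 to 1923). Ccl5, a chemokine of effector T cells and 1 of the genes that define the cluster, was at 778 CPM (666 to 904) against 3455 CPM (3298 to 3617). At least 1 Cd8b1 UMI was found in 7.02% (1.95 to 17.0) and 50.5% (43.3 to 57.7) of the immune cells, and in 5.26% and 33.7% after thinning to 1000 UMIs, which left out no cell. In Sertoli cells, which lack the gene, these shares were 0.128% and 0.397%. Median depth was 1930 and 2378.5 UMIs in immune cells and 1370 and 1548 in Sertoli cells. Cd8a was seen in 7.02% and 31.6% of immune cells (7.02% and 17.9% thinned), whereas Cd4, of helper T cells, was seen in 7.02% and 8.67% (3.51% and 3.57% thinned). In Sertoli cells the shares with Cd8a were 0.128% and 0.0793%, and those with Cd4 the same. Summed over all kept cells, without regard to clusters, Cd8b1 was at 0.700 CPM (0.588 to 0.827) against 3.25 CPM (3.004 to 3.52), and Nkg7, of cytotoxic granules, at 0.429 CPM (0.342 to 0.531) against 2.88 CPM (2.64 to 3.13). Of the 137 and 624 Cd8b1 counts in this sum, only 6 and 255 came from immune cells, so it does not measure killer T cells alone. Over all kept cells Cd4 was higher too, with 14 and 35 counts and a ratio of 2.55 (1.34 to 5.14). So were the macrophage markers C1qa, with 17 and 54 counts, and Lyz2, with 3 and 46. The lymphoid marker Cd79a was lower, with 49 and 15 counts.

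Genes of the interferon response had a median log2 ratio of 0.88 (0.78 to 1.14) in immune cells, at percentile 99.8 of matched random lists, and 15 of 17 measured members lay above the median of all genes in these cells. Among them, Psmb8 of the immunoproteasome was at 178 CPM (126 to 243) against 413 CPM (360 to 471), H2-K1 of class I antigen presentation at 678 CPM (574 to 796) against 1162 CPM (1072 to 1258), and Bst2, which tethers budding viruses, at 18.2 CPM (4.96 to 46.6) against 108 CPM (81.7 to 140). Ifitm2 and Ifitm3, which block entry of viruses, were lower, with log2 ratios of -5.30 and -2.82. Ifitm2 was also lower in other classes, with -1.82 in late spermatocytes. The 9 inflammation genes measured had a median of 0.73 (percentile 94.6) and all lay above that of all genes, with Ccl4 at 1.63 and Tnf at 0.10. The 5 class II antigen presentation genes had a median of 0.34 (percentile 86.5), with H2-Aa at 0.59 and Cd74 at 0.01. H2-Aa in Immune turned to -0.17 at a minimum of 2000 UMIs and to -0.086 with free RNA subtracted. The median of the class II list turned negative under both settings too, and was higher without the cell with the most counts. Genes of heat shock and of the response to tissue dissociation were higher in the same cells, with a median of 1.02 at percentile 100. Germ cell transcripts, which stand for free RNA, reached 69.2% of their whole-library level in immune cells of the library whose label names no diet and 44.8% in the high-fat library. With this RNA subtracted, the medians were 0.21 for the interferon response and -0.01 for inflammation, and both the equal weighting of cells and thinning brought the former to 0.42. The antibody genes Ighg2c, Igkc and Jchain were far higher in the high-fat library, but 1 cell gave 100%, nearly all (99.97%) and 100% of their immune counts there. Jchain had a log2 ratio of at least 3.78 and of -2.23 with doublets kept.

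In Leydig cells, the interstitial cells that make testosterone, all 9 measured genes of steroid hormone synthesis lay below the median of all genes. Their median log2 ratio was -1.32 (-2.16 to -0.63), at percentile 0 of matched random lists. Other lists were low in the same cells, with oxidative phosphorylation at -0.47 and ribosomal proteins at -0.42 (percentile 0), oxidative stress at -0.55 (percentile 0.09) and fatty acid oxidation at -0.86 (percentile 0.375), so the low percentile was not particular to steroid synthesis. Sult1e1, an oestrogen sulfotransferase, stood at -2.12, Hsd17b3, which makes testosterone from androstenedione, at -1.32 (245 CPM, 143 to 393, against 98.4 CPM, 52.4 to 168), Star, which brings cholesterol into mitochondria, at -1.04, Fdx1 at -0.63 and Cyp11a1, of the first step from cholesterol, at -0.42. The genes that define the cluster went the same way, with Hsd3b1 at -2.42, Cyp17a1 at -2.16, Insl3 at -1.42 and Hsd3b6 at -0.99, and without them the median of the list was -1.04. Outside the list, Agt, the precursor of angiotensin, was at 144 CPM (69.2 to 265) against 1037 CPM (871 to 1226), and Ephx1, an epoxide hydrolase, at 649 CPM (474 to 869) against 90.8 CPM (46.9 to 159). Of the other genes the rule names in Leydig cells, H1fnt, Lrrc18, Scp2d1 and Hmgb4 are expressed by spermatids and stood 2.47 to 3.27 higher on the log2 scale, while Serinc3 and Fxyd1 were at -2.19 and -2.06.

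These values rest on 26 and 71 Leydig cells with 69311 and 132108 UMIs, and 1 cell of the library whose label names no diet held 52.4% of the Cyp17a1 counts and 36.8% of those of Hsd3b1. Without the cell with the most counts in each library, the median of the list was -1.08 and Cyp17a1 stood at -1.53. Germ cell transcripts reached 62.2% of their whole-library level in Leydig cells of the library whose label names no diet and 83.8% in the high-fat library, and with them subtracted the median was -0.50. Over all kept cells, which do not depend on the clusters, the same genes were split. Star was at 0.424 CPM (0.338 to 0.526) against 0.902 CPM (0.773 to 1.05) and Cyp11a1 at 0.317 CPM (0.243 to 0.406) against 0.751 CPM (0.633 to 0.884), whereas Cyp17a1 was at 1.02 CPM (0.885 to 1.17) against 0.600 CPM (0.495 to 0.720) and Hsd3b1 at 0.475 CPM (0.383 to 0.582) against 0.235 CPM (0.171 to 0.314).

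**Figure D2:**
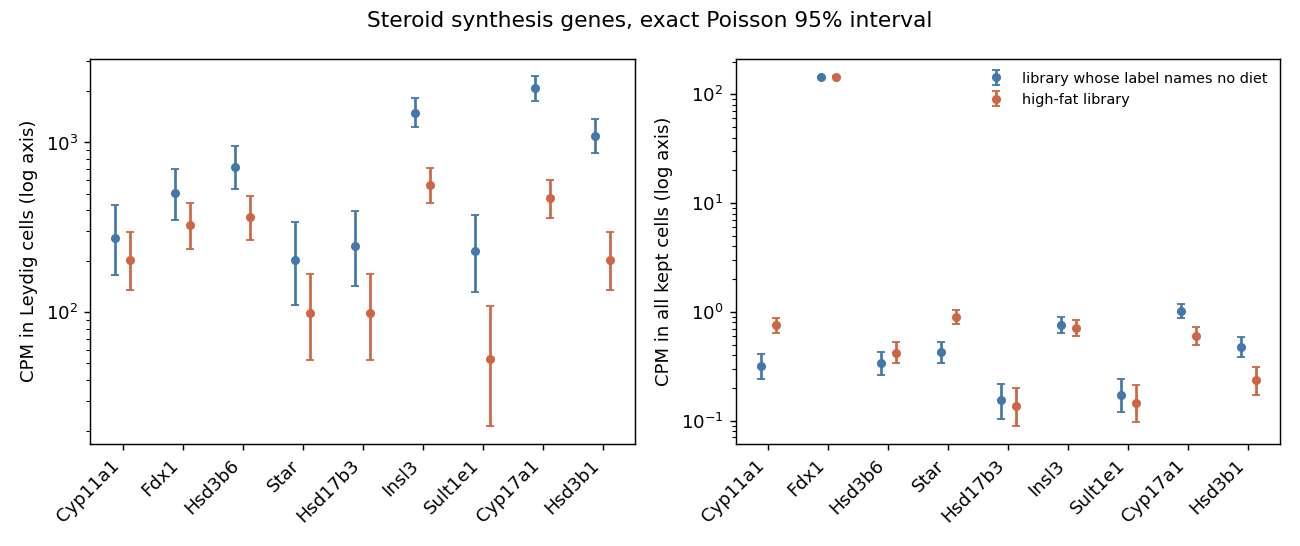
Level in CPM (y axes, log scale) of the 9 measured steroid synthesis genes (x axis) in Leydig cells (left) and in all kept cells (right), for the library whose label names no diet (blue) and the high-fat library (red), with exact Poisson 95% intervals for counting error only. In Leydig cells every gene is lower in the high-fat library (Cyp17a1 2092 against 469 CPM), while over all cells Star and Cyp11a1 are higher there (Star 0.424 against 0.902 CPM).

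In Sertoli cells, the genes of support and hormone response had a median log2 ratio of 0.67 (0.30 to 1.09), at percentile 99.9, and 19 of 23 measured members lay above the median of all genes. Wt1, a transcription factor that keeps Sertoli identity, was at 23.3 CPM (17.2 to 30.8) against 53.6 CPM (45.6 to 62.6), Inha, the inhibin subunit, at 230 CPM (210 to 251) against 451 CPM (427 to 476), and Trf, the iron carrier transferrin, at 17.1 CPM (12.0 to 23.7) against 52.6 CPM (44.7 to 61.5). The desert hedgehog gene Dhh had a log2 ratio of 1.03 and Kitl, the ligand of the receptor on spermatogonia, 1.19. Of the genes that define the cluster, Clu was at 1.29 and Amhr2 at 0.80, and without such genes the list had a median of 0.65. The receptor of follicle-stimulating hormone, Fshr, had a ratio of 1.15 (0.443 to 3.21), within counting error of 1, and the glucose transporter Slc2a3 stood at -0.39 and Cyp26b1 at -0.31. Genes of the blood-testis barrier and junctions had a median of 0.47 (-0.08 to 0.65, percentile 99.04), with the tight junction genes Cldn3 at 2.79 and F11r at 1.06 and, at the other end, Lamb3 at -1.45 and Cdh2 at -0.41. Cst9, a cystatin, was at 163 CPM (147 to 182) against 2422 CPM (2367 to 2479), but was higher in other classes too, with 4.15 in late spermatocytes, while Tnfrsf12a, Spink8 and Cyb5r2 had log2 ratios of -4.09, -2.73 and -2.25. With each cell weighted equally or thinned to 1 depth, the medians were -0.01 and -0.12 for support and -0.12 and -0.14 for junctions, whereas at a minimum of 2000 UMIs they were 1.35 and 0.81, so direction and size depended on how cells were weighted and chosen. Heat shock and dissociation genes had a median of 1.22 (percentile 100) in the same cells, and germ cell transcripts reached 78.1% of their whole-library level in the library whose label names no diet and 70.3% in the high-fat library.

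In myoid and endothelial cells, all 15 contractile genes lay above the median of all genes, with a median log2 ratio of 0.78 (0.34 to 1.35) at percentile 99.99. The class mixes 74 endothelial and 50 myoid cells in the library whose label names no diet and 32 and 30 in the high-fat library, so its make-up differed. Cnn1 and Des, a calponin and desmin of smooth muscle, stood at 2.71 and 1.70. Acta2, Tpm2 and Tagln define the cluster and stood at 1.57, 1.14 and 0.78, and without such genes the median was 0.61. It was 0.0026 when marker, list and leading genes were left out of the clustering, and over all kept cells the list was split, with Des at 0.54, Acta2 at 0.49 and Cnn1 at -0.65. Extracellular matrix genes had a median of 0.35 (-0.29 to 1.03, percentile 99.5), from Nid1 at 1.71 and Tgfbi at 1.36 to Fbln5 at -1.38 and Eln at -1.53. The interferon-inducible genes Ifit1 and Ly6a were at 21.5 CPM (12.0 to 35.5) against 266 CPM (212 to 329) and at 90.4 CPM (69.4 to 116) against 835 CPM (738 to 941), and the Fc receptor Fcgr2b, with 2 counts in the library whose label names no diet, had a ratio of 53.4 (14.0 to 454). Sncg and Mustn1 stood at 3.01 and 2.52 and Haus4 at -2.91. In the interstitial stroma, Sct and Olfml3 stood at 3.75 and 3.33 and Nuggc, which was lower in other classes too, Tmed6 and Ccdc163 at -3.02, -2.77 and -2.57. Heat shock and dissociation genes had medians of 0.34 in myoid and endothelial cells and 0.38 in the stroma, at percentiles 99.7 and 99.9.

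In spermatogonia, stem and progenitor genes had a median log2 ratio of 0.12 (percentile 74.2) and differentiation genes also 0.12 (percentile 90.9), both close to that of all genes. Single members stood apart. Upp1, a uridine phosphorylase of differentiating spermatogonia, was at 13.5 CPM (9.42 to 18.8) against 57.0 CPM (49.1 to 65.9). Bcl6b and Etv5, transcription factors of stem cell self-renewal, stood at 1.74 and 1.10, whereas Ret, a receptor of the niche signal GDNF, and Cdh1 stood at -0.74 and -1.06. Lin28a, which defines the cluster, was at -1.10, and the differentiation list without leading genes had a median of 0.33. Cell division genes had a median of -0.04 (percentile 23.0), with Pcna at 1.01 and Mki67 at -0.51, and the sign of that median turned with doublets kept (0.03) and at 2000 UMIs (0.07). Outside the lists, Tspan7 stood at 5.04 and Fam163a, Abat, AB124611, AA465934 and Sfi1 at -6.28, -5.99, -4.28, -3.96 and -3.85, of which AA465934 was lower in other classes too.

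In spermatocytes, synaptonemal complex and cohesin genes, which pair the chromosomes, had a median log2 ratio of 0.25 (-0.05 to 0.32) at percentile 98.3, with 12 of 19 above that of all genes. Sycp1, of the transverse filament, was the highest at 1.02, while Syce3 and Sycp2 were at -0.17 and -0.18 and turned positive with cells weighted equally (0.06 and 0.10). Meiotic recombination genes had a median of 0.17 (percentile 65.5), with Mei1 at 1.16 and Rnf212, of crossover formation, at -1.12, and thinning took this median to 0.54. The piRNA pathway, which silences transposons, had a median of 0.13 (percentile 87.7), with Pld6 at 0.68 and Pnldc1 at -0.40. Meiotic division genes had a median of 0.09 (percentile 84.8), with the kinase Aurkc at 2.55 (and at 2.27 in round spermatids) and Bub1b, of the spindle checkpoint, at -0.56. In early spermatocytes Sult5a1 and Ppp4r1 stood at 3.99 and 3.69 and Espn and Clasrp at -2.97 and -2.33. Espn was lower in other classes too, with -4.07 in the interstitial stroma and -4.18 in myoid and endothelial cells. Clasrp was also lower in immune cells, at -3.51. Slc25a13 and Ntm were at -3.25 and -2.28 in early spermatocytes and turned to 3.04 and 1.35 with each library clustered on its own.

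In round spermatids, genes of the axoneme and flagellum, the motor of the sperm tail, had a median log2 ratio of -0.11 (-0.23 to -0.04) at percentile 0.23, with 38 of 50 below that of all genes. Rsph1 (ENSMUSG00000024033.10), of the radial spoke, was at 3311 CPM (3298 to 3324) against 1111 CPM (1103 to 1118). It was lower in other classes too, with a log2 ratio of -1.46 in late spermatocytes. Cfap43 stood at -0.87, whereas the dynein heavy chains Dnah1 and Dnah3 were higher, at 1.77 and 1.21. The list had a median of -0.11 in late spermatocytes too, at percentile 0.08. Catsper and sperm ion transport genes had a median of -0.09 (percentile 6.42), with Catsper2 at -0.40 and Catsper1 at 0.28. With each library clustered on its own, the axoneme and Catsper medians were -0.25 and -0.23. Acrosome and egg binding genes had a median of 0.14 (-0.04 to 0.21, percentile 98.9), with Spaca6 at 0.53, Eqtn at 0.45 and Adam3 at -0.45. In elongating spermatids, chromatin condensation genes had a median of 0.06 (percentile 83.1) and outer dense fibre and fibrous sheath genes of 0.04 (percentile 82.2), with Hmgb4 at 0.66 and Hist1h1t at -0.50. The former median was 0.42 with each library clustered on its own, and the directions of Tsga8 (1.43), Tssk4 (0.85), Chd5 (0.61), Smcp (-0.39) and Oaz3 (-0.41), the last 2 of which define a cluster, turned with the clustering.

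Genes of energy metabolism were read in the germ cells. In round spermatids, genes of fatty acid and triglyceride synthesis and storage had a median log2 ratio of 0.34 (0.07 to 0.57) at percentile 99.1, with 20 of 27 above that of all genes. Pnpla2, the triglyceride lipase ATGL, was at 143 CPM (141 to 146) against 253 CPM (250 to 257), the hormone-sensitive lipase Lipe at 11.7 CPM (10.9 to 12.5) against 23.9 CPM (22.8 to 25.0), and Dgat2, which makes triglyceride, at 274 CPM (270 to 278) against 354 CPM (350 to 358). Fasn, the fatty acid synthase, was lower (-0.55), as was Elovl4 (-2.44), and Scd2, at under 1 CPM, was at 1.34. The list thus holds lipases beside genes of synthesis, so its median does not show the direction of triglyceride turnover. Nuclear genes of oxidative phosphorylation had a median of -0.12 (-0.17 to -0.03) at percentile 0.04, with 55 of 76 below that of all genes, and of -0.25 with each library clustered on its own. In late spermatocytes the same list stood at 0.06 (percentile 93.7). Ndufs4 of complex I was at 228 CPM (224 to 231) against 145 CPM (143 to 148), Cycs stood at -0.68, and Cox6b1 and Cox7b were higher at 1.41 and 1.27. Genes of the mitochondrial genome had a median of -0.06 (percentile 31.0), fatty acid oxidation of 0.04 (percentile 45.3) and glycolysis of 0.04 (percentile 62.9). Among their members, Acaa2 was at 1.67, Bdh1, of ketone body use, at -1.62, mt-Nd5 at -0.45, Eno1 at 0.80 and Pgam2 at -0.60. Of the mitochondrial genome list, 7 of 13 members were measured, with an interval of -0.45 to 0.20. Transcripts of that genome made up only 0.0044% and 0.0037% of round spermatid UMIs, so few counts stand behind its median. In late spermatocytes, cholesterol synthesis and uptake genes had a median of 0.10 (percentile 56.0), with Acat2 at 2.79 and Stard4 at -1.72.

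Stress genes as groups were close to all genes of the class in the germ cells for which the lists were fixed. Oxidative stress genes had a median of -0.04 (percentile 13.4) in round spermatids, with the catalase gene Cat at 2.02 and Nfe2l2, the main regulator of this response, at -1.52. Autophagy and ferroptosis genes had a median of -0.06 (percentile 8.87), with Ncoa4, which sends ferritin for breakdown, at 2.33 and the ferritin gene Fth1 at -0.88. Genes of ubiquitin and the proteasome had a median of 0.03 (percentile 57.1), with Uba1 at 1.18 and Psmb5 at -0.44, and the sign of the median turned under most other settings, with -0.12 at Leiden resolution 2. In late spermatocytes, the unfolded protein response had a median of -0.04 (percentile 13.0), with Eif2ak3 at 1.44 and Asns at -1.13. Apoptosis and p53 genes had a median of 0.15 (percentile 71.1), which was 0.47 with each library clustered on its own, with Bbc3 and Pmaip1, pro-apoptotic targets of p53, at 1.98 and 1.67 and the adaptor Fadd at -3.44 (107 CPM, 105 to 109, against 9.90 CPM, 9.25 to 10.6). Fadd was lower in other classes too, with -3.41 in round spermatids. Heat shock and dissociation genes had a median of 0.13 (percentile 69.1), with Jund at 1.40 and Ier2 at -1.59. Ribosomal protein genes had a median of 0.16 (0.10 to 0.31) at percentile 100, with 40 of 61 above that of all genes, and of 0.10 with median-ratio scaling. Rpl26 and Rpl14, the highest at 4.50 and 4.08, were also higher in other classes and are uncertain, because reads could have been shared with processed copies. Over all kept cells, Rpl21, Rps24 and Rps15a stood at 1.19, 0.78 and 0.73. Their copies Rpl21-ps15, Rps24-ps3 and Rps15a-ps8 stood at -11.25, -5.76 and -7.68. Summed with these copies, they stood at 0.77, 0.54 and 0.70, and Rps15a with Rps15a-ps5 or Rps15a-ps6 instead at 0.65 or 0.59. Summing took Rpl14 from 3.87 to 1.09 with Rpl14-ps1, Rps13 from 1.01 to 0.20 with Rps13-ps1 and Rps15 from 0.12 to 0.0072 with Rps15-ps3. The copy Rps13-ps2 went the other way, at 5.22, and summed with it Rps13 stood at 1.04. Read assignment could thus be part of the list's median and percentile, which was not tested.

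**Figure D3:**
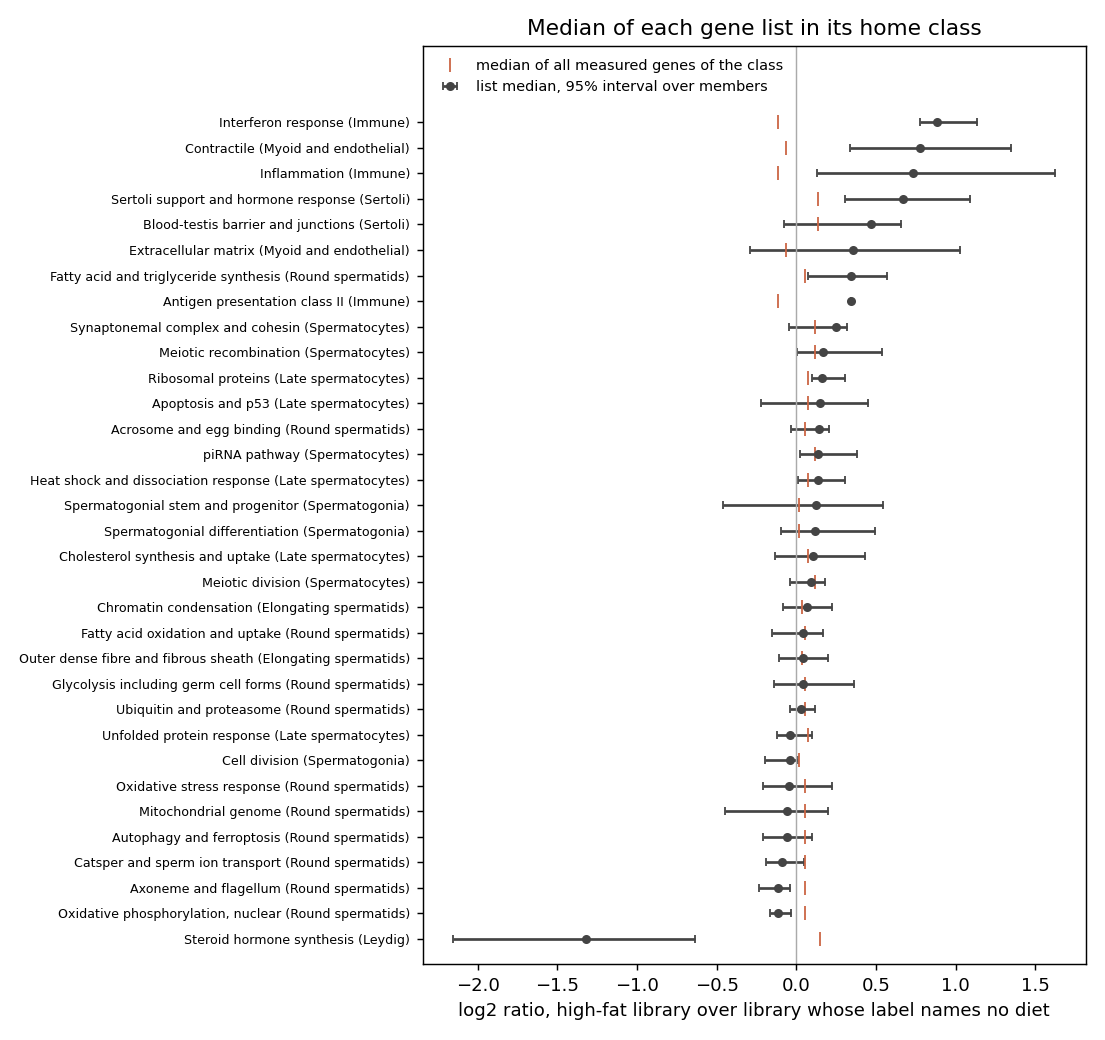
Median log2 ratio of the high-fat library over the library whose label names no diet (x axis) for 33 gene lists in their home class (y axis); points are list medians, bars are 95% intervals over members (none for class II antigen presentation, which has 5), and red ticks are the median of all measured genes of the class. Steroid synthesis sits lowest at -1.32 and the interferon response highest at 0.88. The median of Sertoli support turns sign when cells are weighted equally, and that of inflammation when free RNA is subtracted.

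Some genes differed between the libraries by large ratios in many classes at once. Atp6ap1l was at 0.584 CPM against 330 CPM in late spermatocytes, a ratio of 565 (431 to 756), and at ratios of 39.5 (36.0 to 43.3) in round spermatids and, from 2 counts in the library whose label names no diet, 207 (57.0 to 1712) in Sertoli cells. Dynlt1f, Dynlt1a and Dynlt1b of the dynein light chain family, Rd3, Fxyd2, Sh2d6 and BC061237 were also higher in the high-fat library. The other way, Lsm10 was lower in all classes the rule names it for, with log2 ratios of -4.32 in round spermatids, -4.20 in Sertoli cells and -5.03 in immune cells. Vnn1 and Ubash3a stood at -9.68 and -7.47 in late spermatocytes, with Rtraf-ps, Spin2f and Rdm1 at -7.13, -6.09 and -4.47, and Rag1, Rnaseh2b and Bloc1s6 at -7.87, -5.40 and -5.31 in round spermatids. Summed over all cells, Olfr701 had 3 counts against 3145, a ratio of 1070.4 (366 to 5193), and Agr3 and Ppp1r2-ps1 had log2 ratios of 9.32 and 9.36. Itpr3os had no count against 1384, which makes it at least 471-fold higher against the floor of 3 counts (interval from 383), and Stfa3 had 2107 counts against none, which makes it at least 688-fold lower in the high-fat library against the same floor (interval from 559). Vnn1, Slc45a2 and Zfp990 stood at -9.62, -8.79 and -7.50, and the natural killer receptor gene Klrb1 at 7.79. Several of these genes have near-identical copies, with which reads could have been shared. In somatic classes, free RNA could also have supplied counts of these genes. The median absolute log2 ratio over genes with at least 100 counts was 0.318 for the whole libraries (0.311 to 0.323).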

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

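No planned test stands behind these values, which were read off after the clusters had been seen and were not tested between the libraries. Cluster 3, which got no name and enters no comparison of expression, held 8.76% of kept cells in the high-fat library and 2.66% in the library whose label names no diet, a signal in cells on which no result was planned. Cluster 29, led by transcripts of the mitochondrial genome and also without a name, had a median of 3.25% of UMIs from that genome in the high-fat library and 2.50% in the library whose label names no diet, a signal in cells left out of the classes.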

How the results depend on the processing

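The tests with a minimum of 2000 UMIs, with genes scaled within each library, with marker, list and leading genes left out of the clustering or of the lists, with free RNA subtracted and with the top cell left out were chosen after the results had been seen. No paired analysis was possible because there is 1 library per group. Diet, animal and library are the same split here. Median depth was lowest in Sertoli cells (1370 and 1548 UMIs) and Leydig cells (1503 and 1346 UMIs). All 13 shares and ratios of classes stayed within the interval of their main value at Leiden resolution 0.5. So did the lists with an interval when members needed at least 100 counts or at least 1 count, although wide intervals leave room for large moves. No barcode had under 1000 UMIs or over 20% mitochondrial UMIs, and only 1 and 3 had over 10%, so minima of 200 and 1000 UMIs and other mitochondrial limits left the cells almost as they were and tested nothing. All 12 lists without leading genes stayed within it too, as did those without the top cell. The list of class II antigen presentation has no interval. The median of gene list: Antigen presentation class II was 1.47 without the top cell, -0.52 at 2000 UMIs and -0.33 with free RNA subtracted. Each library clustered on its own gave no myoid and endothelial cell in the high-fat library, and a minimum of 2000 UMIs and the clustering without marker genes gave no Leydig class, so these have no value there. For the values below the cause was not tested.

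With each library clustered on its own, the difference in points for the share of cells, Late spermatocytes, was 6.72 and for the share of cells, Elongating spermatids, -1.24. It was 0.478 for Spermatogonia, -2.0 for Early spermatocytes, 4.72 for Spermatocytes and -5.40 for Spermatids. Ratios of the high-fat library over the other were 1.06 for Spermatocytes per cell of Spermatogonia, 0.731 for Round spermatids per cell of Spermatocytes and 0.936 for Elongating spermatids per cell of Round spermatids. List medians were 0.34 for Synaptonemal complex and cohesin, -0.25 for Axoneme and flagellum, -0.23 for Catsper and sperm ion transport, 0.42 for Chromatin condensation, -0.25 for Oxidative phosphorylation, nuclear, 0.47 for Apoptosis and p53 and -0.12 for Ubiquitin and proteasome. Log2 ratios were 3.04 for Slc25a13 in Early spermatocytes and 1.35 for Ntm in Early spermatocytes. In elongating spermatids they were -0.13 for Chd5, -0.67 for Tsga8, -1.37 for Tssk4, 0.32 for Smcp and 0.44 for Oaz3.

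With doublets kept, the share of cells differed by -0.197 points for Early spermatocytes and -8.03 points for Spermatids, and the ratio for Round spermatids per cell of Spermatocytes was 0.81. Medians were 0.028 for Cell division, -0.20 for Oxidative phosphorylation, nuclear, -0.055 for Ubiquitin and proteasome and 0.50 for Interferon response, and Jchain in Immune was at -2.23. With 4000 variable genes, the share of cells differed by 0.209 points for Late spermatocytes, 2.29 for Spermatocytes and, for the share of cells, Spermatids, -8.54, and ratios were 0.82 for Spermatocytes per cell of Spermatogonia and 0.666 for Round spermatids per cell of Spermatocytes.

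At Leiden resolution 2, the share of cells differed by -3.21 points for Elongating spermatids and 4.68 for Spermatocytes. Ratios were 0.866 for Spermatocytes per cell of Spermatogonia, 0.835 for Round spermatids per cell of Spermatocytes and 0.424 for Elongating spermatids per cell of Round spermatids. Medians were -0.24 for Axoneme and flagellum, -0.22 for Catsper and sperm ion transport, 0.39 for Chromatin condensation, -0.25 for Oxidative phosphorylation, nuclear and -0.12 for Ubiquitin and proteasome. In elongating spermatids, Chd5 was at -0.79, Tsga8 at -1.83, Tssk4 at -2.01, Smcp at 0.70 and Oaz3 at 0.86.

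At a minimum of 2000 UMIs, the share of cells differed by -1.47 points for Elongating spermatids, 3.20 for Sertoli, 0.439 for Spermatocytes and -1.65 for Spermatids. Ratios were 0.754 for Spermatocytes per cell of Spermatogonia and 0.63 for Elongating spermatids per cell of Round spermatids. Medians were 0.075 for Cell division, 0.23 for Chromatin condensation, 1.35 for Sertoli support and hormone response and 0.81 for Blood-testis barrier and junctions, with Tssk4 in Elongating spermatids at -0.38 and H2-Aa in Immune at -0.17. With genes scaled within each library, the share of cells differed by -1.19 points for Elongating spermatids and -0.587 for Spermatocytes, and the ratio for Elongating spermatids per cell of Round spermatids was 0.88. The median of Ubiquitin and proteasome was -0.049, and in elongating spermatids Chd5 was at -0.13, Tssk4 at -0.17, Smcp at 0.094 and Oaz3 in Elongating spermatids at 0.050. With marker, list and leading genes left out of the clustering, the share of cells differed by -2.13 points for Spermatids, the ratio for Round spermatids per cell of Spermatocytes was 1.03 and the median of Contractile was 0.0026.

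Without thinning, the ratio of genes per cell was 0.989 for Leydig, 1.16 for Immune and 0.899 for All, against 1.09, 0.952 and 1.02 at a fixed number of UMIs. The median absolute log2 ratio over genes, All, was 0.324 with cells weighted equally and 0.359 with cells thinned. With cells weighted equally, medians were -0.22 for Cell division, 0.38 for Synaptonemal complex and cohesin, -0.015 for Sertoli support and hormone response, -0.12 for Blood-testis barrier and junctions, 0.42 for Interferon response and 0.33 for Contractile, with Syce3 in Spermatocytes at 0.062 and Sycp2 in Spermatocytes at 0.10. With cells thinned, they were 0.39 for Synaptonemal complex and cohesin, 0.54 for Meiotic recombination, -0.12 for Sertoli support and hormone response, -0.14 for Blood-testis barrier and junctions, 0.42 for Interferon response and 0.31 for Contractile, with Syce3 at 0.0016 and Sycp2 at 0.051. With median-ratio scaling, Ribosomal proteins had a median of 0.10. With free RNA subtracted, medians were -0.50 for Steroid hormone synthesis, -0.0125 for gene list: Inflammation and 0.21 for Interferon response, with H2-Aa in Immune at -0.086.

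Of the named genes, 204 stayed within their main interval at Leiden resolution 2, 37 left it and 5 turned. With cells thinned, 102 stayed, 117 left it and 2 turned, and with each library clustered on its own 164 stayed, 56 left it and 7 turned. With doublets kept these numbers were 231, 40 and 1, with cells weighted equally 217, 53 and 2, at 2000 UMIs 189, 41 and 2, with genes scaled within each library 211, 31 and 4, and with free RNA subtracted 36, 14 and 1. No named gene turned with median-ratio scaling or with marker genes left out of the clustering.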

Other observations

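The tests on paralogs and pseudogenes, on the somatic shares and on free RNA and depth in Leydig cells were chosen after the results had been seen. Genes of the interferon response, measured above in immune cells, were also higher in the high-fat library in myoid and endothelial cells, with a median log2 ratio of 0.79 (0.32 to 1.56, percentile 100) and 20 of 24 members above that of all genes. Medians were 0.73 (-0.47 to 1.78, percentile 99.8) for 10 members in the interstitial stroma and 0.88 (-0.18 to 1.34, percentile 97.9) for 9 in Sertoli cells, with intervals that span 0. In myoid and endothelial cells, germ cell transcripts, which stand for free RNA, reached 40.3% and 30.5% of their whole-library level. In the stroma they reached 73.3% and 64.9%, in both cases lower in the high-fat library. The interferon list was not measured in these classes with free RNA subtracted, a step that lowered its median in immune cells. The 4 class II antigen presentation genes measured in the stroma had a median of 2.76. In germ cells the medians were 0.02 in spermatogonia, 0.05 in round spermatids and 0.31 in late spermatocytes (-0.32 to 0.91, percentile 82.6). Genes of the stress response to heat and dissociation had a median of 0.79 in elongating spermatids (percentile 100) and of 0.05 in Leydig cells (percentile 52.7).

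Among transcripts of the spermatids, some groups were higher and others lower in the high-fat library in classes outside the spermatids. Free RNA could supply these transcripts there. Germ cell transcripts reached 78.1% and 70.3% of their whole-library level in Sertoli cells and 62.2% and 83.8% in Leydig cells. This level was not measured in spermatogonia or early spermatocytes. The values below therefore do not show what these cells express themselves. Outer dense fibre and fibrous sheath genes had a median log2 ratio of 0.87 in spermatogonia, 0.77 in early spermatocytes, 1.00 in Sertoli cells and 1.18 in Leydig cells, each at percentile 100, against 0.04 in elongating spermatids. Chromatin condensation genes had medians of 0.41 in spermatogonia, 0.84 in Sertoli cells, 1.11 in immune cells and 1.76 in Leydig cells. In myoid and endothelial cells the sheath genes stood at -0.04 (percentile 54.6). Axoneme and flagellum genes went the other way, with medians of -0.35 in early spermatocytes, -0.36 in Sertoli cells and -0.83 in immune cells, at percentiles 0, 0 and 0.01, but of 0.43 in Leydig cells. Catsper and sperm ion transport genes had medians of -0.31 (-0.53 to 0.69) in Sertoli cells and -0.14 (-0.24 to 0.22) in spermatocytes, with intervals that span 0.

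A set of 200 genes was taken, as many higher as lower in the high-fat library. They lay furthest apart in the same direction in spermatogonia, late spermatocytes, round spermatids and Sertoli cells, ranked by their smallest distance. They came from about 11950 genes with at least 20 counts in each of these classes, so 200 is not a count of differing genes. The smallest distance on the log2 scale was 1.71 for those higher and 1.37 for those lower in the high-fat library. Thinning left 0.945 (0.929 to 0.968) of the log2 ratio. Random thinning keeps each gene's expected share of a cell's UMIs, so this cannot decide on depth. For the 200 genes, late spermatocytes held 8.76 (7.64 to 9.97) times the UMIs per cell of Sertoli cells. This argues only against free RNA that adds a like number of UMIs to every droplet as their source in late spermatocytes. Median depth was 15885.5 and 20032 UMIs in late spermatocytes against 1370 and 1548 in Sertoli cells. A gene at equal CPM in both classes would thus show such a gap too, and free RNA that rises with depth cannot be told apart. In spermatogonia, round spermatids and Sertoli cells free RNA as the source was not tested. Sertoli cells held germ cell transcripts at 78.1% and 70.3% of their whole-library level, so free RNA could supply counts there. Reads shared with copies could be part of it, since 19% of the genes were pseudogenes against 0.5% to 4% in random sets, and inherited variation between the animals could be another part, since 29.5% had another of them within 5 measured genes on the chromosome against 9% to 22.5%. With neighbours of similar name not counted that share was 24% against 8.5% to 22%, and copy and parent differed in sign for 11 of 13 named copies, though every parent was higher in the high-fat library. Diet and differences in how the libraries were made stay open and were not tested.

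The somatic classes took other shares of the cells in the high-fat library, with immune and Sertoli cells higher. A loss of germ cells that raises every somatic class alike is argued against as the only cause, because myoid and endothelial cells had a share ratio of 0.545 (0.395 to 0.745). Of its parts, the endothelial cells had 0.471 (0.301 to 0.722) and the peritubular myoid cells 0.654 (0.401 to 1.05), which spans 1. The argument rests on the joint clustering, since the high-fat library clustered on its own gave no such class. Differences in how tissue was dissociated or how barcodes were accepted stay open, as does diet, and none of these was tested.

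Steroid synthesis genes were lower in Leydig cells of the high-fat library. The median log2 ratio was -1.18 in thinned cells. Random thinning keeps each gene's expected share of a cell's UMIs, so this cannot decide on depth. Dilution by free RNA cannot be told apart from lower expression, with a median of -0.50 after subtraction and few cells. The 11 Leydig markers outside the list had a median of -1.20, so a lower Leydig content of the droplets that form this cluster could be at work as well. Diet stays open and was not tested.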
